A study of Mus musculus with 12 samples.

How the data were processed

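RNA from cultures of mouse primary embryonic fibroblasts was measured on Affymetrix expression arrays after 12 days with 4-hydroxytamoxifen. The 12 arrays fall into 4 groups of 3, namely wild type (WT), Sos1KO, Sos2KO and Sos1/2DKO, and each array was placed in its group by its sample title. The labels call the arrays of a group biological replicates and do not say which embryo or litter each culture came from, so p-values measure the spread between these cultures.

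Per the submitters' processing notes, the values were made with RMA in R 3.6.3. The deposited value table holds log2 RMA values for 29129 probe sets, and the differences of group means taken from it equal the fold changes of the authors' deposited tables to within 6.22e-09, which fixes the scale and the direction. Array medians ranged from 5.82 to 6.01 on the log2 scale. The authors deposited 3 tables of differential probe sets, 1 for each knockout group against WT, which per the file headers hold a log2 fold change, a mean log2 level, a p-value, an adjusted p-value and a t score and B score from limma; the largest adjusted p-value listed was 0.250. They also deposited enrichment tables for the higher and the lower probe sets of Sos1KO and Sos1/2DKO, whose p-values and q-values are on the log10 scale per the file headers. RMA values carry no detection call, so the 75th percentile of 5222 intron control probe sets, between 5.01 and 5.76 across arrays, served as a guide to weak signal, below which the size of a change is uncertain. The number of arrays limits the precision. The genome build was not given in the sources used here and no coordinates were used.

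Of the 29129 probe sets, 19572 had 1 gene symbol in the platform annotation, 0 had several and 9557 were not named by it. All 19572 symbols were found in the RefSeq gene table of assembly GRCm38.p6, which was used for names only. For the 55 genes with several probe sets, the 1 with the highest mean over the 12 arrays was kept, which left 19505 genes. Levels were fitted with limma 3.58.1 in R 4.3.3, with a mean per group over all 4 groups (8 residual degrees of freedom), empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. The 7 comparisons were each knockout group against WT, Sos1/2DKO against each single knockout, Sos1KO against Sos2KO, and the interaction of the 2 deletions.

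There were 28 gene lists, 17 of pathways and 11 of cell type markers, fixed before the data were examined, with 438 of their 484 members measured and 0 members shared. Each was tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry, and adjusted over the 28 lists of a comparison. Named genes followed a rule fixed at the same time. It takes Sos1 and Sos2 throughout, and per comparison up to 8 rising and 8 falling called genes of largest change whose arrays did not overlap between the 2 groups, leaving out predicted, olfactory, vomeronasal and immunoglobulin segment genes and small RNAs, and up to 4 members per list with the smallest adjusted p. For comparisons that share the WT arrays, 50 sets of unchanged groups, WT included, were simulated. A further 50 simulations, with Sos2KO replicate 3 drawn as a WT array and genes drawn independently, were added after seeing the data.

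The scripts were tested on simulated data built from the real gene means and spreads, with 200 genes of 19505 changed. For Sos1KO against WT, 60% of genes changed by 1 log2 unit and 95% of those changed by 2 were recovered, with 6 false calls. For Sos2KO against WT the shares were 59% and 95% with 12 false calls, and for Sos1/2DKO against WT 59% and 96% with 13. Simulated genes vary independently, unlike the real ones.

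Alternatives fixed at that time were cyclic loess, median centring, a filter on dim genes (mean under the 30th percentile), all probe sets, a trended robust prior, array weights, fits of the 2 groups alone, the replicate number as a block and each array left out in turn. Terms for a spike-in batch, high-GC background, intron signal, embryo sex and macrophage level, fits within batches, and the authors' cutoff of 0.25 were added after seeing the data. The spike-in batch separates the 5 arrays whose poly-A control Dap lay more than 1 log2 unit above every WT array from the other 7. A first test of embryo sex, as a term in the fit, could not move the Sos1KO median because WT and Sos1KO each hold 1 Y-positive array, so comparisons between arrays of the same sex were used after that was seen, and the term was kept beside them for Sos1/2DKO, where the same-sex comparison has 1 WT array.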

Results

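Sos1 and Sos2 encode guanine nucleotide exchange factors that activate RAS. Transcript levels were measured in mouse primary embryonic fibroblasts of 4 genotypes, WT, Sos1KO, Sos2KO and Sos1/2DKO, with 3 arrays in each, after 12 days of 4-hydroxytamoxifen, the ligand used to switch on tamoxifen-inducible Cre. The comparisons ask how the loss of each gene, and of both, changes expression. Correlations between arrays of a group ran from 0.960 to 0.973 in Sos1/2DKO and from 0.986 to 0.990 in WT.

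The deleted genes were lower in the groups named for them. Sos1 had a log2 level of 9.08 ± 0.21 (SD, n = 3) in WT, 8.98 ± 0.35 in Sos2KO, 7.27 ± 0.12 in Sos1KO and 7.52 ± 0.40 in Sos1/2DKO. Sos2 stood at 8.88 ± 0.31 in WT, 8.88 ± 0.15 in Sos1KO, 7.74 ± 0.19 in Sos2KO and 7.86 ± 0.19 in Sos1/2DKO. Every array of a group named for a deletion lay below every array of the other 2 groups for that gene. Signal remained in the knockout groups, and where the probes lie relative to the deleted part was not analysed here.

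**Figure D1:**
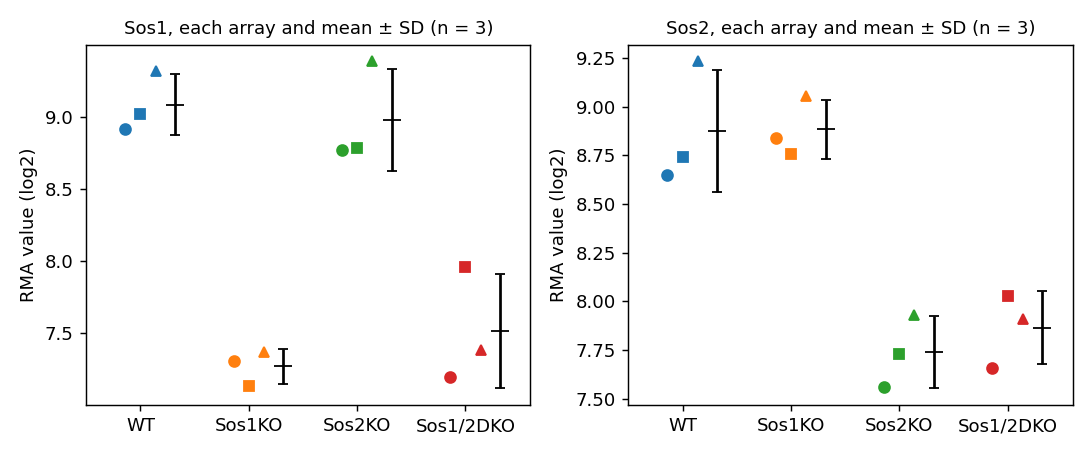
Log2 RMA values of Sos1 (left) and Sos2 (right) on each of the 12 arrays by genotype, with circles, squares and triangles for replicates 1, 2 and 3 and a bar for the group mean ± SD (n = 3). Sos1 is near 7.27 in Sos1KO against 9.08 in WT, and Sos2 near 7.74 in Sos2KO against 8.88 in WT.

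The arrays also differed in ways that the genotype labels do not give. The poly-A control Dap, a bacterial transcript added during labelling, was between 3.89 and 4.13 on 7 arrays and between 6.01 and 9.29 on the other 5, which were Sos1KO replicate 3, all 3 Sos2KO arrays and Sos1/2DKO replicate 1. Background controls of high GC content were at 8.02 and 8.17 on Sos2KO replicates 1 and 2, against 7.03 ± 0.12 (SD, n = 3) in WT. Y-linked genes were expressed on 1 WT, 1 Sos1KO, 2 Sos2KO and 3 Sos1/2DKO arrays, with the midpoint between the lowest and the highest mean as the cutoff. Their mean was 3.56 to 3.95 on the arrays called negative. It was 6.12 and 6.87 on Sos1/2DKO replicates 1 and 3 and 7.16 to 8.10 on the other positive arrays. The call is thus least sure for those 2 replicates. The mean of the macrophage markers was 6.65 ± 1.01 in WT, 6.89 ± 0.56 in Sos1KO, 5.66 ± 0.44 in Sos2KO and 6.02 ± 0.46 in Sos1/2DKO.

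**Figure D2:**
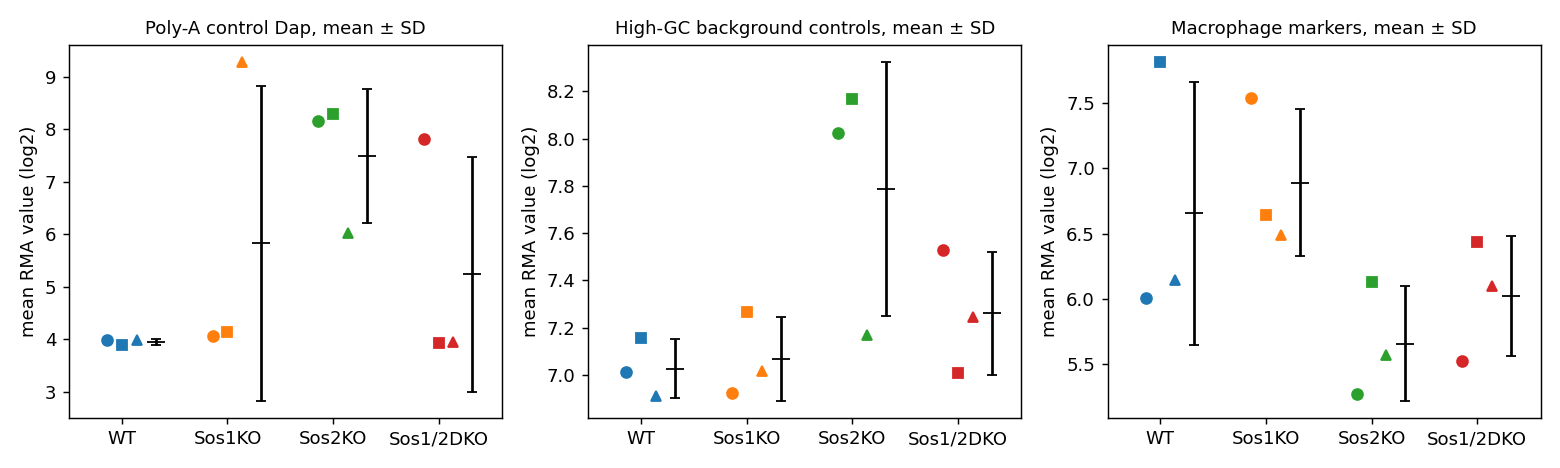
Mean log2 RMA values per array of the poly-A control Dap (left), the high-GC background controls (middle) and the fixed macrophage markers (right) by genotype, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD (n = 3). Dap reaches 9.29 on Sos1KO replicate 3, and the background controls reach 8.17 on Sos2KO replicate 2.

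Genes of DNA replication and mitosis were lower in the Sos1KO cultures than in the WT cultures. Rrm2, a subunit of ribonucleotide reductase, was 3.66-fold lower in Sos1KO than in WT (log2 fold change -1.87, SE 0.22, limma adjusted p = 0.0105), and the replication licensing factor Cdt1 and the helicase subunit Mcm2 fell as well (-1.62 and -1.37). Of the 23 measured members of the replication and E2F list, 9 fell and 14 did not pass over all genes, and 21 fell when adjusted over the list alone. Of the 22 members of the G2/M list, 5 fell, among them the checkpoint kinase Bub1b (-2.31, SE 0.38), Ttk (-1.61) and Cdc20, an activator of the anaphase-promoting complex (-2.07), and 22 fell when adjusted over the list alone. The camera adjusted p was 7.2e-30 and 4.23e-27 for the 2 lists, and 0.0534 and 0.237 as adjusted p with an estimated correlation.

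Across all genes, 121 were called between Sos1KO and WT, 23 higher and 98 lower, and 81 of them differed by at least 2-fold. Among the called genes whose arrays did not overlap between the groups, the largest rises were those of Ehd3 (2.33, SE 0.46), the growth factor Fgf18 (2.02, SE 0.34), Klhl13 (1.76), Pkia, an inhibitor of protein kinase A (1.59), and Sema3b (1.54). Mcm6 (-1.97), Trip13 (-1.83), Ncapg (-1.82) and Racgap1 (-1.77) fell, and so did Sos1 (-1.81, SE 0.22). Ttk, Trip13 and Ncapg were each under the 75th percentile of the intron controls on 1 of 3 Sos1KO arrays. Of the 29 RAS-ERK targets 0 passed over all genes, while 8 fell when adjusted over the list alone; Dusp6, a phosphatase of ERK, had a log2 fold change of -1.30 (SE 0.34, adjusted p = 0.103) and Fosl1 one of -0.99 (SE 0.24, adjusted p = 0.0818). The list's camera adjusted p was 5.11e-06, and the adjusted p with an estimated correlation was 0.237. The lysosome and autophagy list had a median of 0.22 with 0 members past the threshold over all genes and 2 when adjusted over the list alone, with a camera adjusted p of 4.45e-05 and an adjusted p of 0.237 with an estimated correlation. In all, 7 of the 28 lists were called, and 0 with an estimated correlation. The count of 121 genes changed with single arrays. It was 0 without WT replicate 1, WT replicate 3 or Sos1KO replicate 2, 39 without Sos1KO replicate 3 and 192 without Sos1KO replicate 1. Sos1 itself was then not called without WT replicate 1 (-1.90, limma adjusted p = 0.0737), WT replicate 3 (-1.69, 0.0690) or Sos1KO replicate 2 (-1.74, 0.0709). A lost call here thus does not show a lost difference. With the spike-in batch as a term 72 genes were called. Within the arrays without the spike-in 6 were called, from the same 2 Sos1KO and 3 WT arrays as without Sos1KO replicate 3, which gave 39. These 2 fits differ only in the estimate of the spread.

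Between Sos2KO and WT, 0 of 19505 genes were called by limma, while 2711 had an unadjusted p under 0.05, where 975 would be expected with no effect. Sos2 was 2.20-fold lower (log2 fold change -1.14, SE 0.18), with an adjusted p of 0.278. Of the 22 G2/M members 22 had a log2 fold change below 0, with a median of -0.61, and of the 23 replication members 21 did, with a median of -0.43, but 0 of them passed over all genes or adjusted over the list alone. Macrophage markers had a median of -1.02, with 15 of 15 below 0 and 0 past the threshold, and without WT replicate 2 a median of -0.48 with 11 below 0. Interferon-stimulated genes had a median of 0.50, with 1 of 23 past the threshold adjusted over the list alone. Of the 29 RAS-ERK targets 22 were below 0, with a median of -0.38 and 0 past the threshold. Camera called 6 lists, with adjusted p values of 8.68e-06 for G2/M, 9.47e-06 for both the replication and the macrophage list, 0.000997 for the interferon list and 0.0361 for the RAS-ERK targets, and for these 5 the adjusted p with an estimated correlation was 0.822. The camera call of the RAS-ERK targets ended without WT replicate 1 (adjusted p = 0.058), Sos2KO replicate 1 (0.0655) or Sos2KO replicate 2 (0.642, median -0.18), and without Sos2KO replicate 3 their median was -0.59. With the high-GC background in the fit, the call ended and the direction of this list turned. The interferon call ended without Sos2KO replicate 3 (adjusted p = 0.193, median 0.32), and the median was 0.92 without replicate 1 and 0.28 without replicate 2. Without Sos2KO replicate 3, 720 genes were called, 210 higher and 510 lower, and leaving out any other WT or Sos2KO array gave 0, as did each other alternative fixed beforehand. All 3 Sos2KO arrays and 0 WT arrays carried the spike-in, so no value within a batch exists, and with the batch as a term, estimated from the other groups, 1 gene was called (Lcn2, named after its value was seen).

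Members of the cell cycle lists and of the RAS-ERK targets were lower in the Sos1/2DKO cultures than in the WT cultures. All 22 G2/M members fell, with a median log2 fold change of -1.91, including Ttk (-1.86, SE 0.27), Bub1b (-2.48, SE 0.38), the mitotic kinase Aurka (-1.97) and Kif23 (-2.25), and 22 fell when adjusted over the list alone. Of the 23 replication members 18 fell, among them Rrm2 (-1.73, SE 0.22), Gins2 (-1.15), Mcm2 (-1.29) and Cdt1 (-1.35), and 20 fell when adjusted over the list alone. Of the 29 RAS-ERK targets 12 fell and 17 did not pass, and 17 fell when adjusted over the list alone. Dusp6 was lower by a log2 fold change of -2.22 (SE 0.34, limma adjusted p = 0.00582), Phlda1 by -1.82, the transcription factor Myc by -1.70 and the AP-1 component Fosl1 by -1.38. Phlda1 and Ttk were under the 75th percentile of the intron controls on 2 of 3 Sos1/2DKO arrays and Bub1b on 1, so the size of their falls is uncertain. The camera adjusted p was 2.12e-23 for G2/M, 1.54e-22 for replication and 1.15e-12 for the RAS-ERK targets, and the adjusted p with an estimated correlation was 0.253, 0.126 and 0.132.

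**Figure D3:**
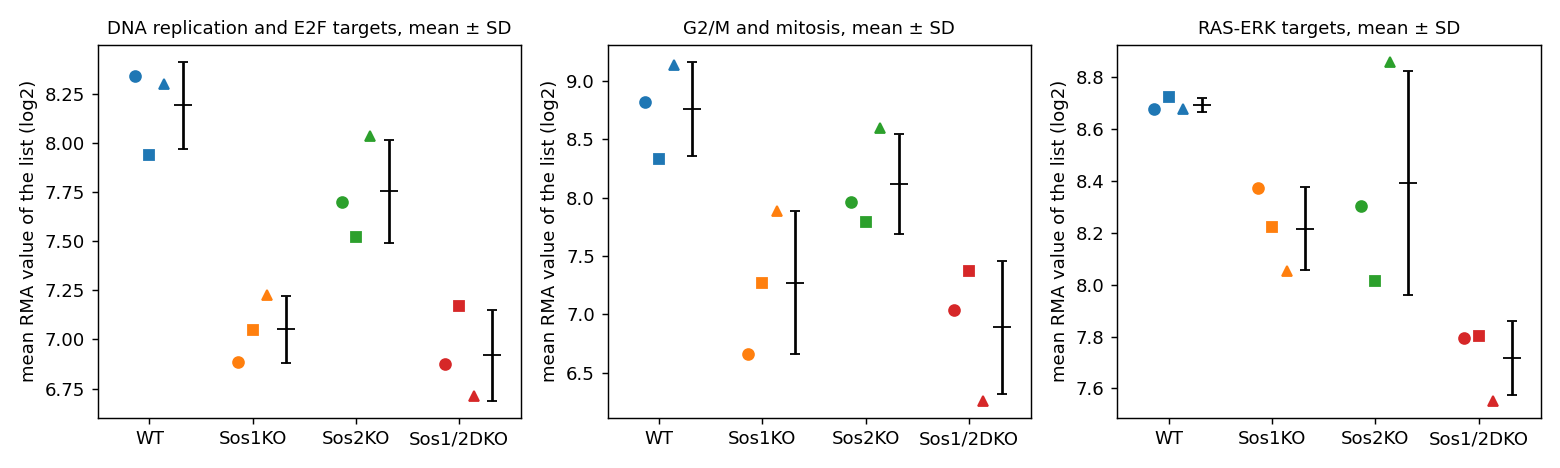
Mean log2 RMA value per array over the fixed lists of DNA replication and E2F targets (left), G2/M and mitosis (middle) and RAS-ERK targets (right), by genotype, with circles, squares and triangles for replicates 1, 2 and 3 and bars for the mean ± SD (n = 3). The G2/M mean runs from 8.34 to 9.13 in WT and from 6.26 to 7.37 in Sos1/2DKO.

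In total, 1158 genes were called between Sos1/2DKO and WT, 347 higher and 811 lower, and 632 differed by at least 2-fold. Ptprq, a receptor tyrosine phosphatase, rose by 13.7-fold (3.78, SE 0.43, limma adjusted p = 0.00347), Igfbp2, which binds insulin-like growth factors, by 10.8-fold (3.43, SE 0.67) and Nell2, a secreted glycoprotein, by 9.20-fold (3.20, SE 0.33). Abi3bp (5.02, SE 1.18), Adgrg2 (3.42) and the collagen-binding proteoglycan Fmod (3.29, SE 0.86) rose too, as did Scg2 (4.24, SE 1.03) and Galnt13 (3.74, SE 0.47), whose WT values lay under the 75th percentile of the intron controls on all 3 arrays. Rgs16, a regulator of G protein signalling (-3.27, SE 0.56), the transferrin receptor Tfrc (-3.13, SE 0.41), the scavenger receptor Olr1 (-3.00), Ankrd1 (-2.94), Tll1 (-2.77), Crabp1 (-2.71), Pclaf (-2.66) and Tfpi2 (-2.66) had the largest falls among the called genes without overlap between the groups, predicted genes and the other classes named above left out. Tfrc was under that percentile on 2 of 3 Sos1/2DKO arrays and Olr1 and Tfpi2 on 1, and Abi3bp was under it on 2 of 3 WT arrays and Ptprq on 1, so the size of these changes is uncertain.

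Other lists moved in part in Sos1/2DKO. Of the RAS pathway components, the 4 named members, picked for the smallest adjusted p, were called in both directions. They do not describe the list as a whole. Nras (log2 level 7.24 against 8.46 in WT), Rasa1 (7.92 against 9.32) and Rras2 (8.93 against 10.1) were lower, and Gab1 (7.92 against 6.54) was higher. In the glycolysis list, the hexokinase Hk2 (-1.41), the lactate transporter Slc16a3 (-1.41) and Pfkp (-0.88) fell and 13 of 16 members did not pass, with a camera adjusted p of 2.34e-05 and an adjusted p of 0.394 with an estimated correlation. Among 8 chondrocyte markers, Col9a1 (1.07), Comp (3.06) and Hapln1 (2.96) rose and 5 did not pass, with a camera adjusted p of 0.00112 and an adjusted p of 0.370 with an estimated correlation; the WT values of Hapln1 were at the level of the intron controls on 3 arrays and those of Comp on 2. Of the 20 senescence-associated secretory genes, Igfbp4 (2.21) and Igfbp5 (2.39) rose, the chemokine Ccl2 fell (-1.27) and 17 did not pass, with a median of -0.15, a mean of 0.035 and a camera adjusted p of 0.889. Of the 24 collagen and extracellular matrix genes, elastin (Eln, 1.92) rose, Fbln1 fell (-1.21) and 22 did not pass, with a camera adjusted p of 0.214. The fibroblast markers Twist2 (-1.94) and Thy1 (-1.54) fell while 7 of 9 did not pass. Macrophage markers had a median of -0.74 with 0 of 15 past the threshold, a camera adjusted p of 0.00539 and an adjusted p of 0.615 with an estimated correlation, and the camera call ended without WT replicate 2 (median -0.10, adjusted p = 0.581) or Sos1/2DKO replicate 1 (median -0.47, adjusted p = 0.117). Of the 28 lists 10 were called, and 0 with an estimated correlation. The count of 1158 fell to 268 without WT replicate 1, 622 without WT replicate 2, 487 without WT replicate 3 and 706 without Sos1/2DKO replicate 3. With a term for embryo sex, all 3 Sos1/2DKO arrays being Y-positive, 404 genes were called. Within the arrays without the spike-in, with 2 Sos1/2DKO and 3 WT arrays, 656 were called. Without Sos1/2DKO replicate 1, which leaves the same arrays of these groups, 789 were.

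The changes in Sos1KO and Sos1/2DKO overlapped. Of the 121 genes called in Sos1KO, 114 were called in Sos1/2DKO with the same sign, 17 higher and 97 lower. Independent lists would share 0.409 and 4.07, values that leave out the shared WT arrays. Simulated unchanged groups, set against a simulated WT group that both comparisons shared, had 0.02 in common. Hardly any gene can be called in unchanged groups, so that count is no measure for the 114. Across genes, which are not independent replicates, the log2 fold changes of the 2 comparisons correlated with r = 0.789 against 0.497 in the simulation, with a covariance of 0.13 against 0.03. The simulated r and covariance hold the sharing of a WT group, but not the real WT arrays, and genes were drawn independently. Part of the excess may still come from the real WT arrays, which are too few to split. For Sos2KO and Sos1/2DKO r was 0.302 against a simulated 0.499 and the covariance 0.048 against 0.032, and no calls can be shared since Sos2KO has 0. For Sos1KO and Sos2KO, set against the same WT arrays, r was 0.142 against a simulated 0.500 and the covariance 0.017 against 0.032.

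Sos1/2DKO and Sos1KO differed in 1 called gene, Sfrp2, which encodes a secreted modulator of WNT signalling. Its log2 level was 9.80 ± 0.84 (SD, n = 3) in Sos1/2DKO and 6.55 ± 0.47 in Sos1KO, a rise of 3.25 (SE 0.38, limma adjusted p = 0.0214). Sos2 had a log2 fold change of -1.02 (SE 0.18, adjusted p = 0.266). All 29 RAS-ERK targets had a log2 fold change below 0, with a median of -0.42; 0 passed over all genes or adjusted over the list alone, and Dusp6 stood at -0.93 (SE 0.34, adjusted p = 0.615) and Myc at -0.77 (SE 0.27, adjusted p = 0.608). The list's camera adjusted p was 1.07e-08, and the adjusted p with an estimated correlation was 0.455. Of the 22 G2/M members 21 were below 0 with a median of -0.34 and 0 past the threshold, with a camera adjusted p of 0.000944 and an adjusted p of 0.557 with an estimated correlation. That camera call ended without Sos1KO replicate 3 (median -0.090, adjusted p = 0.56) or Sos1/2DKO replicate 3 (median -0.050, adjusted p = 0.676), and the median was -0.63 without Sos1KO replicate 1 and -0.54 without Sos1/2DKO replicate 2. In this comparison 1404 genes had an unadjusted p under 0.05 against 975 expected. The count was 0 without Sos1KO replicate 1 or replicate 3 and 10 without Sos1/2DKO replicate 2; without Sos1KO replicate 2 Wfdc1 joined Sfrp2, without Sos1/2DKO replicate 1 Slc26a7 did, and without Sos1/2DKO replicate 3 the called gene was Cxcl15 instead. These other genes were named after their values were seen.

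Against Sos2KO, Sos1/2DKO differed in 1197 genes, 650 higher and 547 lower, a balance that turned to 443 higher and 758 lower with median centring. Of the named RAS pathway components, Gab1 (log2 level 7.92 against 6.34 in Sos2KO) and Braf (9.32 against 8.07) were called higher. Nras (7.24 against 8.31) and Rasa1 (7.92 against 9.08) were called lower. RAS-ERK targets were lower for 9 of 29 members and higher for 1, with Fosl1 at -1.70 (SE 0.24, limma adjusted p = 0.00551), Myc at -1.69, Etv4 at -1.40 and the phosphatase Dusp4 at -2.57, and 14 fell when adjusted over the list alone. The replication and the G2/M list each had 9 members that fell, with Gins2 at -0.98, Mcm2 at -1.06, Aurka at -1.72 and Plk1 at -2.14. FOXO targets rose for 5 of 16 members, with Foxo1 at 1.61 and Sesn3 at 1.71. The camera adjusted p was 1.31e-06 for the RAS-ERK targets, 1.57e-12 for replication and for G2/M and 2.85e-05 for the FOXO targets, and in the same order the adjusted p with an estimated correlation was 0.388, 0.269, 0.388 and 0.269. Among called genes without overlap, the largest rises were in Abi3bp (5.45, SE 1.18), Scg2 (4.40, with Sos2KO at the level of the intron controls), the imprinted gene Mest (4.37, SE 0.70), Islr (4.33), Rgs5 (4.23) and Nell2 (4.13, SE 0.33), and the largest falls in Crabp1, which binds retinoic acid (-4.27, SE 0.72), Rgs16 (-3.20), Nup62cl (-3.13, with Sos1/2DKO at the level of the intron controls), Crmp1 (-2.78) and the skeletal actin Acta1 (-2.67). Crmp1 was under the 75th percentile of the intron controls on 1 of 3 Sos1/2DKO arrays and Abi3bp on 1 of 3 Sos2KO arrays, so with Scg2 and Nup62cl the size of these changes is uncertain. The Sos1/2DKO arrays also varied widely for Scg2 (SD 3.01, n = 3). The count fell to 339 without Sos2KO replicate 1 (163 higher, 176 lower) and 443 without Sos2KO replicate 2 (197 higher, 246 lower), and to 0 without both. Without Sos1/2DKO replicate 2 more genes were lower too (375 higher, 461 lower). It was 289 with the spike-in batch as a term, 239 with the high-GC background as a covariate (70 higher, 169 lower), 603 with the intron signal (253 higher, 350 lower) and 1 within the arrays with the spike-in, where Sos1/2DKO has 1 array (Lcn2, named after its value was seen).

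Sos1KO and Sos2KO differed in 836 genes, 546 higher in Sos1KO and 290 lower. Sos1 was lower (-1.70, SE 0.22) and Sos2 higher (1.15, SE 0.18) in Sos1KO. Of the RAS-ERK targets, Fosl1 (log2 level 7.70 against 9.02 in Sos2KO) and Etv4 (6.66 against 7.95) were called lower in Sos1KO. Fos was called higher (9.84 against 7.22). Of the RAS pathway components, Braf (9.51 against 8.07), Gab1 (7.46 against 6.34) and Rasgrp3 (8.44 against 7.13) were called higher. Replication genes fell for 6 of 23 members, with Cdt1 at -1.29 and Mcm2 at -1.14, cholesterol synthesis genes for 4 of 19, with Lss at -1.26 and Fdps at -1.27, and FOXO targets rose for 3 of 16, with Klhl24 at 1.71 and Sesn3 at 1.64. The camera adjusted p was 3.12e-09, 1.81e-05 and 2.96e-05, and the adjusted p with an estimated correlation 0.509, 0.602 and 0.509. Without Sos2KO replicate 2 the cholesterol median went from -0.55 to -0.33. Of 15 macrophage markers, lysozyme (Lyz2, 3.17, SE 0.80) was higher in Sos1KO and 14 did not pass, while 7 rose when adjusted over the list alone, with a camera adjusted p of 1.39e-05 and an adjusted p of 0.602 with an estimated correlation. Foxp2 (3.69), Chodl (3.06), Mest (2.98), Lilrb4a (2.97), Rspo3 (2.92), Rgs5 (2.72) and the growth factor Bmp4 (2.62) showed, with Lyz2, the largest rises among called genes without overlap, and Crabp1 (-3.89, SE 0.72), Dkk2 (-2.05), Crmp1 (-2.04) and Tfpi2 (-2.02) the largest falls. Dkk2 was under the 75th percentile of the intron controls on 2 of 3 Sos1KO arrays and Crmp1 and Tfpi2 on 1, and Lilrb4a on 1 of 3 Sos2KO arrays. The count of 836 was 3 without Sos1KO replicate 2, 24 without Sos1KO replicate 3, 18 without Sos2KO replicate 1, 12 without Sos2KO replicate 2 and 1870 without Sos2KO replicate 3. It was 12 with the spike-in batch as a term, 33 within the arrays with the spike-in, where Sos1KO has 1 array, 1 with the high-GC background as a covariate and 0 with the macrophage level as a covariate.

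The interaction of the 2 deletions, which asks whether the effect of losing both differs from the sum of the single effects, gave 0 called genes by limma, with 962 at an unadjusted p under 0.05 against 975 expected. Interferon-stimulated genes had a median interaction of -0.46 with 0 of 23 past the threshold, a camera adjusted p of 0.000983 and an adjusted p of 0.723 with an estimated correlation. The camera call ended without Sos2KO replicate 3 (median -0.27, adjusted p = 0.118), and the median was -0.77 without Sos2KO replicate 1. For the RAS-ERK targets the median was -0.12, with 0 of 29 past the threshold and a camera adjusted p of 0.0603. Fosl1 stood at -0.71 (SE 0.34, adjusted p = 0.907) and Myc at -0.76 (SE 0.38, adjusted p = 0.907). Without Sos1/2DKO replicate 3, 1 gene was called (Cxcl15, named after its value was seen).

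The authors' deposited table for Sos1KO lists 2306 probe sets, 886 higher and 1420 lower, the 1 for Sos2KO lists 59, 12 higher and 47 lower, and the 1 for Sos1/2DKO lists 2507, 927 higher and 1580 lower. A limma fit of the 2 groups over all probe sets at an adjusted p under 0.25 gave those counts and the same probe sets. All 121 genes called here in Sos1KO and all 1158 called in Sos1/2DKO are in the authors' deposited tables with the same direction. Both rest on the same arrays and values, so the shared direction is built in. A listed adjusted p under 0.05 was held by 7 probe sets in Sos1KO, 0 in Sos2KO and 286 in Sos1/2DKO. Control probe sets made up 301 of the 2306 for Sos1KO and 285 of the 2507 for Sos1/2DKO. Of the 59 probe sets in the authors' deposited table for Sos2KO, 49 are control probe sets, 9 are genes tested here and 1 of these is Sos2. In the authors' deposited table of enrichment for the lower probe sets, the leading term was the Reactome cell cycle set in both groups, with 190 of 551 genes listed in each. In the authors' deposited table for the higher probe sets, lysosome led in Sos1KO (25 of 124 genes, log10 p -12.8) and extracellular matrix organization led in Sos1/2DKO (38 of 271 genes, log10 p -12.9).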

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

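The tests of macrophage content and embryo sex against the cell cycle pattern, and the simulation of Sos2KO replicate 3, were chosen after the results were seen. The signals below lie in control probe sets that no comparison uses, above their level on the WT arrays. The poly-A control Dap was at 9.29 on Sos1KO replicate 3, 8.16, 8.29 and 6.01 on Sos2KO replicates 1, 2 and 3, and 7.82 on Sos1/2DKO replicate 1, against at most 3.98 on the WT arrays. High-GC background controls were at 8.02 and 8.17 on Sos2KO replicates 1 and 2 and at 7.53 on Sos1/2DKO replicate 1, above 7.40, the WT mean plus 3 SD. These 2 controls part the arrays in a way that overlaps with Sos2KO.

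The fall of the 45 fixed cell cycle genes was weighed against other differences between the arrays. In Sos1KO the median log2 fold change of -1.41 became -1.31 with the macrophage level in the fit (-1.41 to -1.23 without each array in turn), -1.51 with the spike-in batch (-1.71 to -1.34) and -1.38 between the 2 arrays of each group without Y-linked expression (-1.71 to -0.88). In Sos1/2DKO the median of -1.66 became -1.89 (-2.16 to -1.61), -1.77 (-2.17 to -1.55) and -1.80 (-1.95 to -1.58), the last between the 3 Y-positive Sos1/2DKO arrays and the 1 Y-positive WT array. Since that WT array cannot be left out, sex was also put in the fit for Sos1/2DKO, which gave -1.82 (-1.96 to -1.57 without each array in turn, with 26 of the 45 genes called against 40). The macrophage level differed little between WT (6.65 ± 1.01) and Sos1KO (6.89 ± 0.56), so its term could move the Sos1KO median little. No WT array carried the spike-in, so its term rested on Sos1KO replicate 3 and Sos1/2DKO replicate 1. Within the arrays without the spike-in the medians were -1.52 in Sos1KO and -1.68 in Sos1/2DKO, 2 arrays each against 3 of WT. These values argue against macrophage level, spike-in batch and sex each as the whole cause. A lower share of cycling cells after loss of Sos1 is a candidate explanation that was not tested, and neither were differences in culture density or passage.

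The 836 genes called between Sos1KO and Sos2KO may owe part of their difference to the arrays. Of these, 546 were higher and 290 lower in Sos1KO, so a single sign given to all would already match most of them. The shares of the 836 genes given next were not taken over all genes and have to be read beside that split. A trend fitted within the other groups' arrays predicted the sign of 77.4% of them from the high-GC background (58.7% to 81.7% without each of 6 arrays in turn), of 77.8% from the macrophage level (69.0% to 84.1%) and of 78.5% from the spike-in batch (65.3% to 79.4%, 3 arrays). The median absolute log2 fold change of 1.00 (median SE 0.21) became 0.73 (SE 0.26), 0.92 (SE 0.27) and 0.93 (SE 0.26) with these in the fit, so the calls ended through a wider error and, for the background, also through a smaller difference. None of the 3 can be told apart from the deletions, because each differs between the 2 groups and the arrays that could separate them are few.

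The 720 genes called between Sos2KO and WT without Sos2KO replicate 3 had a median absolute log2 fold change of 0.92, against 0.20 for replicate 3 set against the WT mean, a gap that is in part built in, since the genes were called on the other 2 arrays. In replicate 3, 81.8% kept their sign, against 63.3% (61.2% to 66.0%) in 50 simulations of it as a further WT array, which called more genes (a mean of 1960.1, median absolute difference 0.22), so the shares are not from like lists and decide nothing. Of the 720 genes, 510 were lower and 210 higher, so a trend giving all the same sign would match most, and no share over all genes was taken. From the trend within 6 Sos1KO and Sos1/2DKO arrays, the high-GC background, highest on replicates 1 and 2, predicted the sign of 87.2%. This share ran from 70.3% to 87.8% without each of those arrays in turn. The spike-in batch predicted the sign of 64.4% (34.4% to 75.6%). Neither can be told apart from a difference between the Sos2KO cultures, since 2 arrays carry the pattern. Sos2 itself was at -0.95 from the WT mean in replicate 3 against -1.23 in replicates 1 and 2, a smaller gap than that of the 720 genes.

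Regrouping the 6 arrays of a comparison gives 10 splits, too few for a share under 0.05. A split that mixes 2 differing groups puts their difference, whatever its cause, into the spread, so low counts there are in part built in. The real groups gave 121 genes for Sos1KO against WT, with at most 2 in the other splits and 1 split as large, the real one. The same held for Sos1/2DKO against WT (1158, others at most 0), Sos1/2DKO against Sos2KO (1197, others at most 2) and Sos1KO against Sos2KO (836, others at most 0). For Sos2KO against WT all 10 splits gave 0, and for Sos1/2DKO against Sos1KO 4 of the 10 gave at least 1, with 2 as the highest. For the interaction, 100 of 100 regroupings of the 12 arrays gave at least the real count of 0, as any must, so this says nothing about chance. The highest of the others, 357 genes, points to a structure of the samples, which can be the effect of a single deletion, since regrouping mixes such effects into the interaction; which it was, was not tested.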

How the results depend on the processing

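Settings for the spike-in batch, background, intron signal, sex, macrophage level, fits within batches, the 2 left-out Sos2KO arrays and the authors' cutoff were chosen after seeing the data. The cause of a changed count was not tested unless given. Counts under cyclic loess, the filter on dim genes and the trended robust prior stayed within 1.5 times those reported. For Sos1KO against WT the count of 121 became 73 with median centring, 30 over all probe sets, 1680 with array weights, 274 in the 2 groups alone, 72 with the spike-in term, 212 with the background, 230 with the intron signal, 41 with sex and 68 with the macrophage level, and 6 within the arrays without the spike-in. For Sos2KO against WT the count of 0 became 1 with the spike-in term (Lcn2, -4.60). For Sos1/2DKO against WT 1158 became 1799 with array weights, 747 in the 2 groups alone, 404 with sex and 656 within the arrays without the spike-in. For Sos1/2DKO against Sos1KO the 1 gene became 0 over all probe sets, with array weights, in the 2 groups alone, with the background, with sex and within the arrays with the spike-in. For Sos1/2DKO against Sos2KO 1197 became 781 with array weights, 466 in the 2 groups alone, 289 with the spike-in term, 239 with the background, 603 with the intron signal, 682 with sex, 0 without Sos2KO replicates 1 and 2 and 1 within the arrays with the spike-in. For Sos1KO against Sos2KO 836 became 522 over all probe sets, 2540 with array weights, 12 with the spike-in term, 1 with the background (Sos1), 15 with the intron signal, 300 with sex, 0 with the macrophage level, 0 without Sos2KO replicates 1 and 2 and 33 within the arrays with the spike-in. The interaction count of 0 became 1 with the spike-in term (Lcn2, 4.57). Where 1 array of a group is left, it is assumed to vary like the other groups. At an adjusted p under 0.25 the counts were 1112, 3829, 4618 and 4294 for Sos1KO and Sos1/2DKO against WT and Sos1/2DKO and Sos1KO against Sos2KO, and the authors' 2-group fit over all probe sets gave 2306, 59 and 2507 for Sos1KO, Sos2KO and Sos1/2DKO against WT.

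Without each array in turn, counts ran from 0 to 192 for Sos1KO against WT, 0 to 720 for Sos2KO against WT, 268 to 1504 for Sos1/2DKO against WT, 0 to 10 for Sos1/2DKO against Sos1KO, 339 to 1660 for Sos1/2DKO against Sos2KO, 3 to 1870 for Sos1KO against Sos2KO and 0 to 1 for the interaction. With the replicate number as a block, 65 genes were called for Sos1KO against WT and 1 for the interaction (Sfrp2), and the other counts stayed within 1.5 times. Same-numbered arrays were not paired by their deviations, since 6 of 18 such pairs correlated above 0.1, the mean r was -0.0222 and 2 of the 12 arrays correlated best with their own number. The same-numbered pairs of WT and Sos2KO were all among these 6 (r = 0.111, 0.108 and 0.305), and there the block gave 0 called genes. Median centring, which shifted array medians by -0.12 to 0.07, moved the share of lower genes from 70.0% to 80.3% for Sos1/2DKO against WT and from 45.7% to 63.1% against Sos2KO, and cyclic loess moved it from 34.7% to 44.8% for Sos1KO against Sos2KO. The overlap of 114 genes became 0 at an adjusted p under 0.01, where Sos1KO has 0 calls. Of the 61 list calls, 0 held with an estimated correlation, 10 held with fry, which asks another question, 60 with the block and 47 with cyclic loess.

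Among the named genes and called lists, signs turned for Sos1 and Sos2 in comparisons where they were not called, and for 6 lists. Sos2 in Sos1KO against WT became -0.0089 with median centring, -0.10 without WT replicate 1, -0.059 without WT replicate 2, and -0.077 without Sos1KO replicate 3 and within the arrays without the spike-in, and ran up to 0.19 without WT replicate 3. Sos1 in Sos2KO against WT became 0.057 with the spike-in term, 0.50 with the background, 0.18 with the intron signal, 0.30 without Sos2KO replicates 1 and 2 and 0.011 without WT replicate 3, and ran down to -0.31 without Sos2KO replicate 3. Sos1 in Sos1/2DKO against Sos1KO became -0.17 within the arrays with the spike-in. Sos2 in Sos1/2DKO against Sos2KO became -0.10 with the background, -0.047 with the intron signal, -0.063 without Sos2KO replicates 1 and 2 and -0.080 within the arrays with the spike-in. The interaction of Sos1 became -0.10 with the background and -0.056 without Sos2KO replicates 1 and 2, and that of Sos2 -0.12 with the background, -0.076 with the intron signal, -0.071 without those 2 arrays and -0.061 without WT replicate 3, and ran up to 0.23 without WT replicate 1. With the background in the fit, adjusted p values with a turned sign were 0.354 for RAS-ERK targets in Sos2KO against WT, 0.126 for collagens and 0.802 for skeletal muscle markers in Sos1KO against Sos2KO and 0.540 for collagens in the interaction. With the macrophage level, which is built from them, macrophage markers gave 0.980 in Sos2KO against WT and 0.809 in Sos1KO against Sos2KO. Genes near the level of the intron controls limit what these arrays can show.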

Other observations

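Histone genes were looked at as a group picked, like the terms tried on it, after their values were seen, with no test of the group. Of 61 measured genes with histone symbols, 43 were lower and 2 higher in Sos1KO than in Sos2KO (limma), with a median log2 fold change of -1.10, and among the genes named for this comparison were H2bc18 (-1.96, SE 0.48), H4c6 (-1.93, SE 0.41) and H4c3 (-1.82, SE 0.36). Against WT, 29 were lower and 1 higher in Sos1/2DKO (median -0.85), 5 were lower in Sos1KO (median -0.92) and 0 were called in Sos2KO (median 0.19, with 8 of 61 below 0). The medians kept their sign in these 4 comparisons under cyclic loess and median centring, and that of Sos1/2DKO against Sos1KO, 0.054 with 0 called, turned to -0.00072 with centring. Between Sos1KO and Sos2KO 0 of the 61 were called with the high-GC background, the macrophage level or the spike-in batch in the fit (medians -0.78, -0.92 and -0.92), 1 was lower with the intron signal and 22 were lower and 1 higher with sex. The Sos2KO median against WT turned to -0.080 with the background and -0.090 with the spike-in batch. Between Sos1/2DKO and WT, 2 were lower with sex in the fit, against 29 without it. The median there was -0.87 against -0.85, and the median SE 0.27 against 0.23. With the background, macrophage level, spike-in batch and intron signal, 31, 30, 30 and 27 were lower. The mean level over the 61 genes was 9.49 to 9.69 on the WT arrays, 9.56 to 9.99 on the Sos2KO arrays, 8.50 to 9.04 on the Sos1KO arrays and 8.64 to 9.08 on the Sos1/2DKO arrays. Many of these genes are near-identical copies, so a probe set can read several of them, and values for single members are uncertain.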
